A study of Triticum aestivum with 16 samples.

How the data were processed

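RNA-seq was done on bread wheat seedlings with stranded messenger RNA libraries. AK58 leaf, root and shoot apex were taken at 2 weeks, and AK58 axillary buds of 1.0 to 2.0 cm at 6 weeks, after 30 days at 4 °C. ZM7698 shoot apices and axillary buds of 1.0 to 2.0 cm, from WT and from the hexa-mutant M6 of TaSPL7 and TaSPL15, were taken at 2 weeks. Each group held 2 libraries. The submitters' processing notes name Trimmomatic for trimming, HISAT2 2.0.5 for alignment and StringTie 1.3.3b for quantification. The genome build is not given in the sources used here. DAP-seq and ATAC-seq data of the same project were not used here.

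The deposited ZM7698 values are TPM and have the same sum in each library. The deposited AK58 values carry the same name but are not TPM: they are a signal equal to whole reads divided by 1 factor per library, so that the reads could be recovered. In each AK58 library 100% of values were whole within 0.001 reads, the values summed to between 43023989.8 and 62824961, and the recovered reads to between 51497044 and 79585209. The AK58 values are called normalised reads here. They are not corrected for gene length, so they were compared between tissues and not between genes of different length, and the shares of homoeologs and subgenomes in AK58 carry this limit. The counting program behind the AK58 reads is not given in the sources used here. Both sets list 120744 identifiers, of which 107891 are wheat gene identifiers and 12853 are noncoding RNA identifiers. Reads shared between near-identical copies of a gene could be split between them by the quantification, so values of single homoeologs carry that uncertainty.

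Each set of 8 libraries was fitted on its own with limma 3.58.1 in R 4.3.3, on log2 of the value + 1 with an intensity trend, and the sets were never fitted together. Tests were two-sided with Benjamini-Hochberg adjustment, and a call needed an adjusted p under 0.05 and an absolute log2 fold change of at least 1. A gene was called enriched in a tissue when it was called higher there than in each of the other 3 tissues. ZM7698 genes needed at least 1 TPM in at least 2 libraries, which left 50878. The filter for AK58 was changed once the unit was known, from 1 TPM to 10 normalised reads in at least 2 libraries, which left 69525. With all libraries in 1 fit, a group with a large spread, such as AK58 root, widens the error in the other contrasts of its set. The mean that named AK58 identifiers needed was changed with it, and the trend in the ratio test was dropped later. The other tests, gene lists and alternatives were fixed before the data were examined, except for the additions given here and below. Counts per chromosome and the shares of called genes under 0.1 TPM were not in that plan. Nor was the comparison of bud and apex changes between the cultivars.

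The reference gene table matched 0 of the identifiers in the files and held no transcripts. For this reason 12 of the 13 planned gene lists were not tested, and triads were not built across the genome. The list that was used holds 34 identifiers of 12 regulators of tillering, flowering and the spike, fixed from published identifiers. Neither the files nor the reference pair these identifiers with names, so the names rest on that literature alone. The 10 regulators with 3 copies served as triads. By the rule for named genes, the text gives each listed regulator that was called, TB1, VRN1 and FUL2 in any case, and for each contrast the 2 identifiers with the largest increase and the 2 with the largest decrease. Those identifiers had to be called, with replicates that did not overlap between groups and a mean of at least 5 TPM, or 50 normalised reads in AK58, in the higher group. SVP1-6A, SVP1-6B, FT1, RHT1-4A and Q-5A were added after their values were seen. TraesCS6D02G287500 and TraesCS6D02G294900 were also added then, as called genes on either side of SVP1-6D by identifier order.

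The list was tested as a group with camera in limma, with its preset correlation of 0.01 and with an estimated one. Triads with a summed mean over 0.5, in TPM in ZM7698 and in normalised reads in AK58, were put in the nearest of 7 ideal categories. This cut was not changed for the AK58 unit. Changes in homoeolog ratios were tested with limma on differences of log2 values, without the intensity trend that was planned, because the list gives few pairs. Overlaps of calls and counts per chromosome were tested with Fisher's exact test. The other settings tried were added values of 0.1 and 5, no filter, stricter filters of 5 TPM and 50 normalised reads, median centring, quantile normalization, no intensity trend, a fit with the contrasted groups alone, no minimum fold change, the replicate number as a block, and each library left out in turn. After the data were seen, a quasi-likelihood test in edgeR 4.0.16 on the recovered AK58 reads, an AK58 filter of 1, a fit without both root libraries and a ratio test with each pair's own spread were added. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.

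The procedure was tested on simulated data with 50 changed genes at each size. The changed genes were drawn from those whose mean log2 value lay above that of 5 TPM, or of 50 normalised reads in AK58. Recovery of genes between the filter and that level was not simulated. In the AK58 bud and apex contrast, 0%, 8%, 78% and 74% of genes were recovered at an absolute log2 fold change of 1, 2, 4 and 6, with 3 false calls. In the M6 apex contrast the shares were 44%, 92%, 98% and 100%, with 7 false calls. These shares hold for a contrast with few changed genes, where the adjustment is stricter than in one with many. Floors for genes at 0 in AK58 used 3 reads per library and cover counting error only.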

Results

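Messenger RNA was sequenced from bread wheat in 16 libraries that form 8 groups of 2. In the cultivar AiKang58 (AK58) the groups were leaf, root, shoot apex and axillary bud. In the cultivar Zhengmai7698 (ZM7698) they were shoot apex and axillary bud of the wild type (WT) and of M6, a line mutated in all copies of TaSPL7 and TaSPL15. These genes encode SQUAMOSA PROMOTER BINDING PROTEIN-LIKE (SPL) transcription factors, which act in shoot branching and flowering. The AK58 tables corresponded to 51497044 to 79585209 reads per library, with 67174 to 75358 genes above 0. The ZM7698 tables gave 70100 to 73715 genes above 0, and their depth is unknown. Transcripts of TaSPL7 and TaSPL15 were not analysed here, because the tables and the reference do not pair these names with identifiers, so the genotype labels were not checked on the targeted genes. Nothing in the labels says that replicates came from separate plants, so the p-values measure only the spread between these samples.

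The first comparison asked how axillary buds of AK58 differed from shoot apices. All copies of VRN1, a MADS-box gene that promotes flowering after cold, rose in the bud. The A copy, VRN1-5A, stood at 1465 ± 101 normalised reads (SD, n = 2) in the bud and 43.0 ± 16.0 (SD, n = 2) in the apex, a log2 fold change of 5.10 ± 0.61 (SE; limma adjusted p = 0.00375). VRN1-5D stood at 146 ± 15.2 (SD, n = 2) in the bud and had 0 reads in both apex libraries, so it was at least 57.9-fold higher with a floor of 3 reads per library (limma adjusted p = 0.000830). VRN1-5B stood at 132 ± 19.3 (SD, n = 2) in the bud, against 0.835 and 1.70 in the apex libraries (limma adjusted p = 0.00110). The AK58 buds came from plants that were 6 weeks old and had spent 30 days at 4 °C, whereas the apices came from untreated plants of 2 weeks, so tissue, age and cold treatment changed together.

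Some copies of VRT2 and SVP1, MADS-box genes of the SHORT VEGETATIVE PHASE family, fell in the same buds. VRT2-7A decreased by 2.07 ± 0.33 on the log2 scale (SE; limma adjusted p = 0.00965), VRT2-7B by a log2 change of -2.01 ± 0.46 (SE; limma adjusted p = 0.0306) and SVP1-6A by a log2 change of -1.61 ± 0.26 (SE; limma adjusted p = 0.00963). WAPO1-7A, an F-box gene that affects spikelet number, had a log2 change of -2.66 ± 0.52 (SE; limma adjusted p = 0.0189). The TB1 copies, which encode a repressor of bud outgrowth, did not pass the test: the log2 changes were -1.33 for TB1-4A (limma adjusted p = 0.131), -0.42 for TB1-4B (limma adjusted p = 0.623) and -0.89 for TB1-4D (limma adjusted p = 0.274). FUL2, a close relative of VRN1, lay below the expression filter, with 15.0 and 8.49 normalised reads of FUL2-2A in the apex libraries and 1.44 and 0 in the bud libraries. Of the 34 listed gene copies of regulators of tillering, flowering and the spike, 23 were measured, 3 rose and 4 fell. Adjusted over the list alone, 3 rose and 6 fell. The list as a group did not pass camera, a test of the list against the other genes (p = 0.0868; p = 0.587 with an estimated correlation).

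Across all genes, 6746 were higher and 5646 lower in the AK58 bud than in the apex, of 69525 tested. TraesCS2D02G425200 stood at 25294 ± 3258 normalised reads (SD, n = 2) in the bud, against 0 and 1.70 in the apex libraries. TraesCS2A02G427200 stood at 14692.5 ± 2023 (SD, n = 2) in the bud and had 0 reads in the apex. In the other direction, TraesCS6B02G000100 stood at 4342 ± 655 (SD, n = 2) in the apex, against 0 and 2.46 in the bud libraries, and TraesCS5A02G003200 at 1261 ± 412 (SD, n = 2), against 0 reads in the bud. The counts moved with single libraries: 2308 genes were higher without bud replicate 1 and 11408 without root replicate 1, and 685 were lower without apex replicate 2 and 12304 without root replicate 1. The VRN1-5A call held with each library left out. VRN1-5B and VRN1-5D held in the 6 such fits where they passed the expression filter, and without either bud library they were not tested. The calls of VRT2-7A, VRT2-7B, SVP1-6A and WAPO1-7A were lost in 3 of 8, 6 of 8, 3 of 8 and 1 of 6 such fits, with adjusted p up to 0.0883, 0.183, 0.0786 and 0.118 (limma) and the direction kept; WAPO1-7A was not tested without either apex library.

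**Figure D1:**
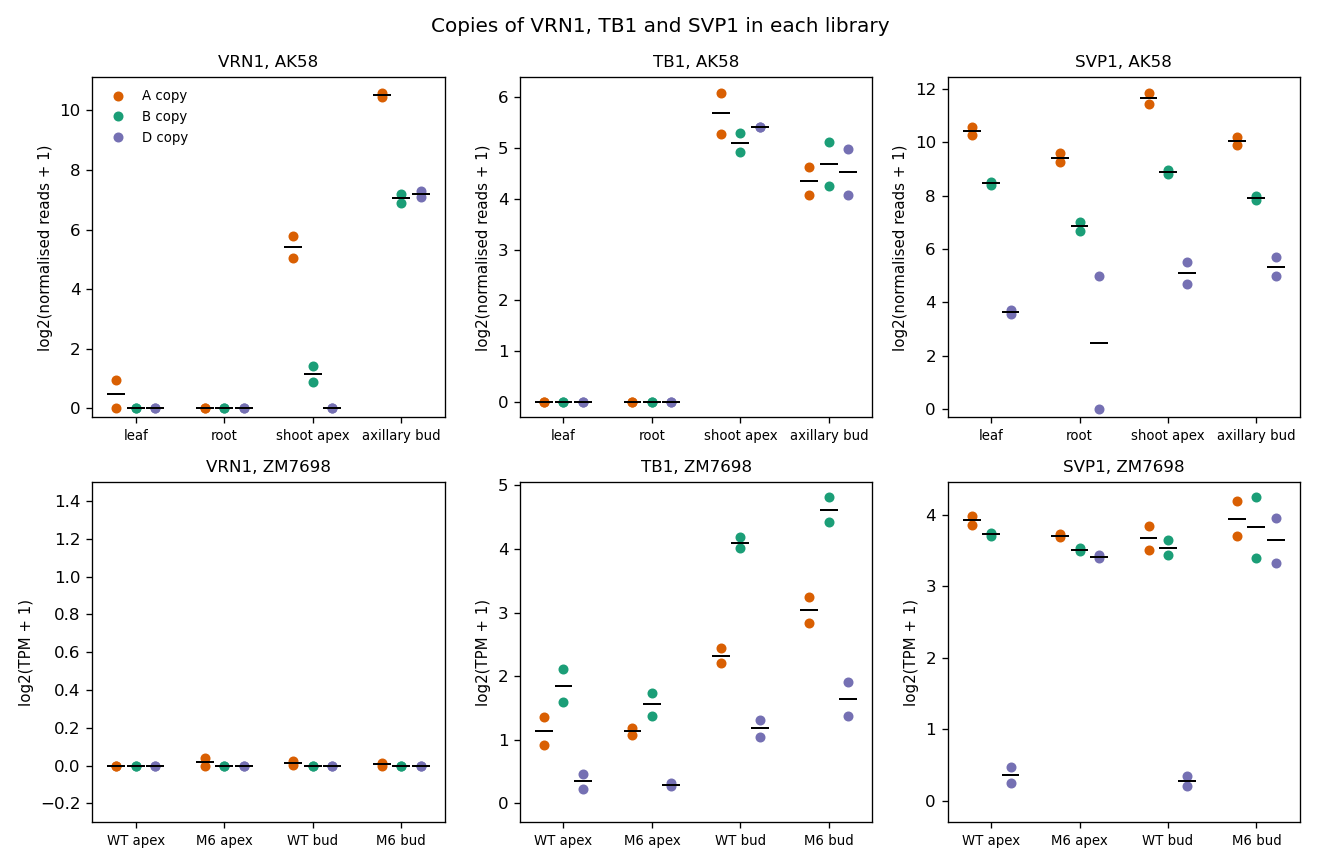
Copies of VRN1, TB1 and SVP1 in each library (points, coloured by subgenome) with the mean of the log2 values (black bars, n = 2), as log2 of normalised reads + 1 in AK58 (top) and of TPM + 1 in ZM7698 (bottom). VRN1 is high in the AK58 bud, TB1 is at 0 in AK58 leaf and root, and the D copy of SVP1 is near 0 in ZM7698 WT but not in M6.

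The tissue comparison asked which genes were higher in one AK58 tissue than in each of the others. Root had 4926 such genes, leaf 2731, shoot apex 1926 and axillary bud 812. Among the regulators, the VRN1 copies were bud-enriched, and VRT2-7A, VRT2-7B, SVP1-6A and WAPO1-7A were apex-enriched. PPD1-2D, a pseudo-response regulator of the photoperiod pathway, was leaf-enriched at 484 ± 62.5 normalised reads (SD, n = 2), against 195 ± 73.9 (SD, n = 2) in the root, 149 ± 1.06 (SD, n = 2) in the apex and 59.5 ± 0.631 (SD, n = 2) in the bud. Its smallest log2 fold change, against root, was 1.35, and its highest adjusted p over the other tissues was 0.0408 (limma). FUL3-2A, a MADS-box gene related to VRN1, was root-enriched at 13.5 ± 2.18 normalised reads (SD, n = 2) and had 0 reads in the other tissues. TB1 had 0 reads in every leaf and root library, and TB1-4A stood at 52.3 ± 20.8 (SD, n = 2) in the apex, at least 17.2-fold above leaf and at least 20.7-fold above root with the same floor. FT1, the mobile flowering signal, had at most 1.64 normalised reads in any AK58 library.

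The root replicates stood apart from each other. Their correlation across genes was 0.770 on the log2 scale, against 0.965 to 0.980 for the other AK58 tissues. RHT1-4A, which encodes a DELLA repressor of gibberellin responses, stood at 82.3 normalised reads in root replicate 1 and 3101 in root replicate 2. Without both root libraries, a choice made after the data were seen, 8385 genes were leaf-enriched, 6854 apex-enriched and 3069 bud-enriched among the remaining tissues, and 10411 were higher and 10636 lower in bud than in apex. The enriched counts also moved with single libraries: 166 for leaf without leaf replicate 1, 2276 for root without root replicate 2, 110 for apex without apex replicate 2 and 37 for bud without bud replicate 1.

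In ZM7698 the bud and the apex were both sampled at 2 weeks, with no cold treatment given in the labels. TB1 rose in the WT bud. TB1-4B stood at 16.1 ± 1.46 TPM (SD, n = 2) in the bud and 2.66 ± 0.899 TPM (SD, n = 2) in the apex, a log2 fold change of 2.25 ± 0.23 (SE; limma adjusted p = 0.0209). TB1-4A stood at 4.01 ± 0.571 TPM (SD, n = 2) and 1.23 ± 0.476 TPM (SD, n = 2), a log2 fold change of 1.18 ± 0.21 (SE; limma adjusted p = 0.0366). TB1-4D had a log2 fold change of 0.83 and did not pass the test (limma adjusted p = 0.103). It stood at 1.27 ± 0.293 TPM (SD, n = 2) in the bud and 0.275 ± 0.145 TPM (SD, n = 2) in the apex. The apex lay below the 1 TPM added before the logarithm, so 0.83 understates the change. VRN1-5B and VRN1-5D were listed at 0 in every ZM7698 library, and VRN1-5A reached at most 0.0288 TPM. FUL2 copies were listed at 0 or reached at most 0.00555 TPM. Of the 34 listed gene copies 15 were measured, 2 rose and 0 fell in limma. Adjusted over the list alone, the counts were also 2 and 0. The list as a group did not pass camera (p = 0.557; p = 0.871 with an estimated correlation).

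Across all genes, 821 were higher and 450 lower in the WT bud, of 50878 tested. TraesCS5D02G013400 stood at 126 ± 50.8 TPM (SD, n = 2) in the bud and 2.49 ± 1.73 TPM (SD, n = 2) in the apex, and TraesCS5A02G007900 at 114 ± 45.1 TPM (SD, n = 2) and 2.21 ± 1.37 TPM (SD, n = 2). TraesCS3A02G530800 stood at 3.44 ± 2.48 TPM (SD, n = 2) in the bud and 350.2 ± 350.5 TPM (SD, n = 2) in the apex. TraesCS3A02G397300 was listed at 0 in the bud and at 68.2 and 46.7 TPM in the apex libraries. Of the 1207 genes with a ZM7698 call that were also tested in AK58, 1073 (88.9%) had the same sign there, against 65.0% of all genes tested in both sets. In AK58, 530 were called in the same direction, against 113.8 if the calls were independent, and 13 in the opposite direction. These calls rested on few libraries: without WT apex replicate 2 or without WT bud replicate 2, limma called 0 genes in either direction, with 5498 and 6166 genes at an unadjusted p under 0.05, and without WT bud replicate 1 it called 5 higher and 0 lower, with 5950. It called 283 higher and 769 lower without WT apex replicate 1, 501 and 180 without M6 apex replicate 1 and 498 and 180 without M6 apex replicate 2. The TB1-4B call was lost in 3 of 8 such fits (adjusted p up to 0.166, limma) and the TB1-4A call in 6 of 8 (adjusted p up to 0.216, limma), with the direction kept.

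The mutant comparison asked which genes changed where both SPL genes were mutated. SVP1-6D, the D copy of SVP1, rose in M6 in both tissues. In the apex it stood at 9.67 ± 0.229 TPM (SD, n = 2) in M6 and 0.290 ± 0.148 TPM (SD, n = 2) in WT, a log2 fold change of 3.05 ± 0.21 (SE; limma adjusted p = 0.00852). In the bud it stood at 11.8 ± 3.85 TPM (SD, n = 2) and 0.211 ± 0.0807 TPM (SD, n = 2), a log2 fold change of 3.37 ± 0.21 (SE; limma adjusted p = 0.00519). WT lay below the 1 TPM added before the logarithm, so both values understate the change, and with 0.1 added they were 4.70 and 5.24 (limma adjusted p = 0.0132 and 0.00737). SVP1-6A and SVP1-6B did not pass the test, with log2 fold changes of -0.21 and -0.21 in the apex and 0.27 and 0.29 in the bud. TB1 did not pass it either: in the bud the log2 fold changes were 0.72 for TB1-4A (limma adjusted p = 0.268), 0.52 for TB1-4B and 0.46 for TB1-4D, and in the apex they lay between -0.29 and -0.0047. VRN1 and FUL2 stayed below the expression filter in both genotypes. TraesCS6D02G287500 and TraesCS6D02G294900, on either side of SVP1-6D (TraesCS6D02G293200) by identifier order, were called lower in M6 in both tissues. In the apex they fell from 21.3 and 4.17 TPM in WT to 0.00403 and 0 TPM in M6. They were not close neighbours of SVP1-6D, which had no called gene within 5 tested genes. Chromosome 6D held 6 called genes, against 3.72 from its share of tested genes (Fisher's exact test, two-sided, adjusted p = 0.659). Whether loss of the SPL genes or a differing chromosome segment underlies the SVP1-6D change was not tested. The SVP1-6D call was lost in the apex without any 1 of the 4 apex libraries (limma adjusted p up to 0.161, without M6 apex replicate 1) and in the bud without either WT bud library (limma adjusted p up to 0.0883, without WT bud replicate 1), with the direction kept.

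Of the 15 listed gene copies measured, SVP1-6D was the 1 that rose in each tissue, and 0 fell. Adjusted over the list alone the counts were the same. In the bud the list as a group passed camera with its preset correlation (p = 2.84e-07), and this call was lost with p = 0.205 with an estimated correlation. In the same tissue M6 replicate 1 lay above replicate 2 for all 15 of these genes, for example at 30.2 against 19.0 TPM for Q-5A, an AP2-type gene of spike shape. In the apex the list did not pass (p = 0.457; p = 0.837 with an estimated correlation).

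In the M6 apex 40 genes were higher and 28 lower than in WT, and in the M6 bud 41 were higher and 34 lower. TraesCS1D02G037300 rose from 1.90 ± 0.0752 TPM (SD, n = 2) to 389 ± 11.1 TPM (SD, n = 2) in the apex, a log2 fold change of 7.07 ± 0.17 (SE; limma adjusted p = 3.79e-05), and by a log2 fold change of 7.77 ± 0.17 in the bud (SE; limma adjusted p = 3.08e-05). TraesCS5B02G061400 was listed at 0 in WT and stood at 41.5 ± 1.23 TPM (SD, n = 2) in the M6 apex, and TraesCS3D02G504400 was listed at 0 in the WT bud and stood at 37.6 ± 1.29 TPM (SD, n = 2) in the M6 bud. TraesCS5B02G260600 stood at 99.3 ± 5.88 TPM (SD, n = 2) in the WT apex and at 0.127 and 0 TPM in the M6 apex libraries. TraesCS5B02G080800 stood at 30.2 ± 0.171 TPM (SD, n = 2) in the WT apex and at 0 and 0.00701 TPM in the M6 apex libraries. Both of these were also called lower in the M6 bud. Chromosome 5B held 24 of the 93 called genes on numbered chromosomes, against 5.03 from its share of tested genes (Fisher's exact test, two-sided, adjusted p = 2.10e-09). This test was not planned, and genes are not independent of each other, so its p-value cannot be taken at face value.

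**Figure D2:**
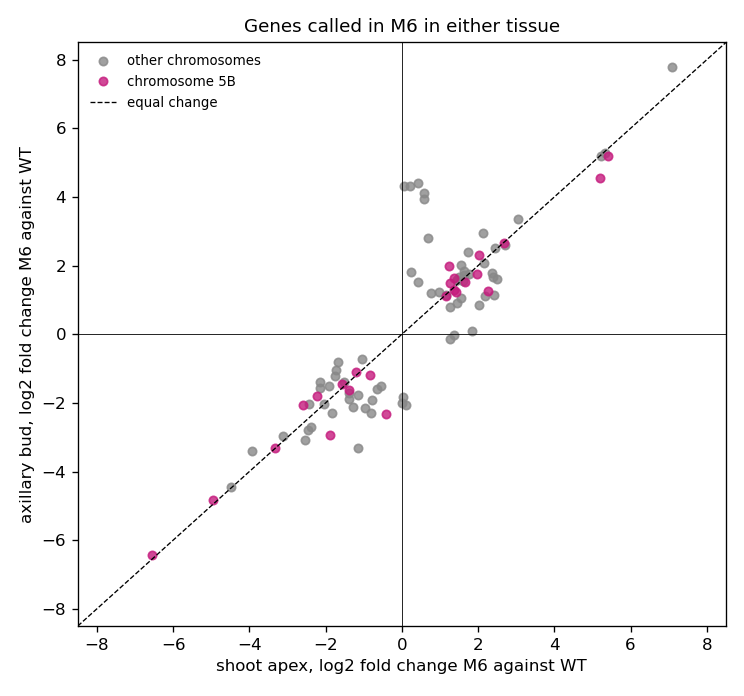
Log2 fold change of M6 against WT in the shoot apex (x axis) and the axillary bud (y axis) for the 94 genes called in either tissue, with genes on chromosome 5B in magenta and a dashed line at equal change. Of the 94 genes, 90 have the same sign in both tissues.

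The effects of M6 in the apex and the bud were also compared with each other. In the same direction, 28 genes were called higher in both tissues, against 0.0322 if the calls were independent (Fisher's exact test, p = 4.97e-83), and 21 lower, against 0.0187 (Fisher's exact test, p = 8.19e-65). The contrasts use different libraries but share 1 estimate of the spread for each gene, and genes are not independent of each other. These p-values therefore cannot be taken at face value. Limma called 0 genes for a difference between the effects in bud and apex, where 4105 of 50878 had an unadjusted p under 0.05 and the smallest adjusted p was 0.413. The counts moved with single libraries: without M6 apex replicate 1, 5 genes were higher in the M6 apex and 14 were shared, and without WT apex replicate 2, 8 were lower. Without each of the other ZM7698 libraries in turn, the M6 apex had between 8 and 49 higher and between 8 and 37 lower genes. In the bud, 1398 were higher and 614 lower without M6 bud replicate 2, where the test of the difference called 1634, against 11 higher without WT bud replicate 1 and 9 lower without WT bud replicate 2.

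**Figure D3:**
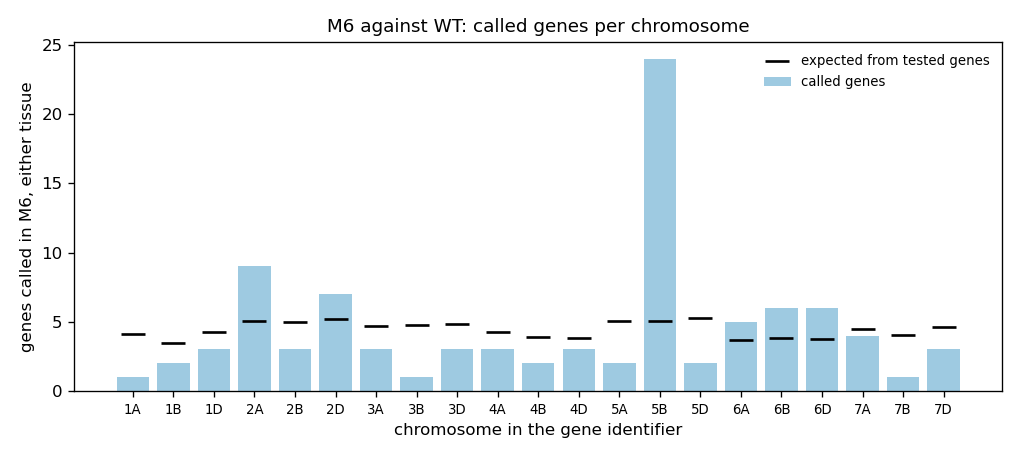
Number of genes called in M6 in either tissue on each chromosome (bars) and the number expected from its share of tested genes (black dashes). Chromosome 5B has 24 called genes, against 5.03 expected.

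The series title concerns expression divergence between the A, B and D subgenomes, so the copies of the listed regulators were compared within each triad. In ZM7698 WT the D copy gave 1.09% of the summed SVP1 expression in the apex and 0.929% in the bud, and in M6 it gave 30.1% and 29.3%, so that SVP1 moved from the D-suppressed to the balanced category in both tissues and in each replicate. The SVP1 ratios A to D and B to D changed by -3.27 and -3.26 (log2) in the M6 apex, with a limma adjusted p of 1.07e-36 for both. That value shares the spread across pairs that are few and not independent. With the spread of each pair alone, an alternative chosen after the data were seen, the adjusted p was 8.51e-05 and 0.000129. In the bud the changes were -3.10 and -3.08 (log2; adjusted p = 3.95e-32 for both with limma, and 8.77e-05 and 0.000135 with the spread of each pair alone). The added 1 TPM understates these changes too, with the D copy below it in WT. These were the 2 of 18 tested pairs in the apex and the 2 of 15 in the bud that passed. The SVP1 ratio A to B changed by only -0.00207 in the apex and -0.0136 in the bud. The passing ratios and the change of category therefore restate the rise of SVP1-6D and are not separate results. In AK58 the SVP1 triad was A-dominant in all tissues, with D shares of 0.664% to 3.06%.

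In the AK58 bud the A copy gave 84.0% of VRN1 expression, the B copy 7.57% and the D copy 8.39%. Between bud and apex 4 of 30 ratios passed, those of VRN1 A to D (log2 change -2.09) and B to D (-1.31) and of FUL2 A to B (-1.85) and A to D (-2.98). VRN1-5D had 0 reads in the apex and the FUL2 copies at most 15.0 normalised reads, so these ratios depend on the value added before the logarithm, and 2 passed when 0.1 was added. FUL2-2D had 0 reads in every apex and bud library. The FUL2 A to D change is therefore that of FUL2-2A alone, and no ratio to the D copy was measured. TB1 was balanced in the AK58 apex and bud, and in ZM7698 it was D-suppressed in the WT apex and B-dominant in the WT bud. Of the list triads classified per group, 11 of 27 were balanced in AK58 and 13 of 21 in ZM7698, and the replicates fell into different categories for 10 and 4 of them. The 2 sets cannot be compared in this count. AK58 includes leaf and root, and its cut of 0.5 normalised reads let in triads near 0, such as FT1 in the bud with a summed mean of 0.822. Over all genes on numbered chromosomes, the mean shares of summed expression on A, B and D were 33.4%, 31.8% and 34.8% in AK58 and 34.1%, 31.6% and 34.3% in ZM7698. These shares are given without a test.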

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

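TB1-4A and TB1-4D had bud to apex changes of opposite sign in the 2 cultivars, but neither AK58 change passed the test. TB1-4A had a log2 change of -1.33 ± 0.51 (SE) in AK58 and 1.18 ± 0.21 (SE) in ZM7698 WT, and TB1-4D had -0.89 ± 0.50 (SE) and 0.83 ± 0.22 (SE). The mean of TB1-4D in the ZM7698 WT apex, 0.275 TPM, lay below the added 1 TPM, so 0.83 understates that change. Both were flagged because bud and apex replicates did not overlap in either cultivar and their order was opposite in AK58 and ZM7698. That separation was the rule for flagging, and with 2 libraries per group it can arise by chance, so it adds no support. The difference between the cultivars was not tested. Of these 4 changes, only that of TB1-4A in ZM7698 passed. TB1-4B, with -0.42 ± 0.50 (SE) in AK58 and 2.25 ± 0.23 (SE) in ZM7698 WT, where it passed, had replicates that overlapped between bud and apex in AK58. The AK58 buds were also older and had been kept in the cold.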

How the results depend on the processing

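The tests without both root libraries, with edgeR and with the spread of each ratio alone were chosen after the results were seen. Of 283 checks of 27 named-gene results, 233 kept direction and call, 50 lost the call and 0 reversed. The 27 results had been chosen as called in these data, and the identifiers among them also for replicates that did not overlap. Reversals were therefore unlikely from the start, and their absence is weak evidence. With 2 libraries per group and unknown depth in ZM7698, the limits lie in the spread between replicates, and a lone sample was assumed to vary like the other groups when its replicate was left out. Where no construction of the setting shows it, the cause of a change was not tested.

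With 0.1 added, 21 genes were lower in the M6 bud and 2 AK58 ratios passed. With 5 added, 399 and 123 genes were higher and lower in the ZM7698 bud against apex, 21 and 14 in the M6 apex, 24 higher in the M6 bud, and 25 were shared. Without a filter, the ZM7698 bud counts were 373 and 163 and the M6 bud had 22 lower. With stricter filters, which test fewer genes, the ZM7698 bud had 291 lower, the M6 apex 19 higher and 12 lower, the M6 bud 21 and 14, and 21 were shared. With only the contrasted groups in the fit, which leaves fewer samples, AK58 bud against apex had 9770 lower, the M6 apex 11 higher and 9 lower, the M6 bud 5 and 5, and 8 were shared. Without a minimum fold change, 1477 were higher in the ZM7698 bud. Without both root libraries, 8385, 6854 and 3069 genes were enriched in leaf, apex and bud, and AK58 bud against apex had 10411 higher and 10636 lower. With edgeR, 894 genes were apex-enriched and 484 bud-enriched, and 3082 were lower in the AK58 bud. In that contrast 8572 genes were called by both, of 8632 with edgeR and 12392 with limma. The group test of the regulators in the M6 bud gave p = 0.205 with an estimated correlation. Without the 100 highest genes, the B share in AK58 was 32.0%, and the A, B and D shares in ZM7698 were 33.3%, 32.7% and 34.0%.

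With the replicate number as a replicate block, the ZM7698 bud against apex had 13 higher and 7 lower, the M6 apex 15 and 11, the M6 bud 16 and 14, and 19 were shared. The calls of TB1-4A (limma adjusted p = 0.0751) and TB1-4B (limma adjusted p = 0.0540) and of the 4 named identifiers in the ZM7698 bud against apex (limma adjusted p from 0.0540 to 0.0694) were lost in that fit, with the same fold changes. Deviations of same-numbered libraries correlated between -0.308 and 0.430, and the libraries share only a number.

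Leaving out each library in turn gave 166 to 3876 leaf-enriched, 2276 to 7104 root-enriched, 110 to 5865 apex-enriched and 37 to 2966 bud-enriched genes. AK58 bud against apex ranged from 2308 to 11408 higher and 685 to 12304 lower, and ZM7698 WT from 0 to 1009 higher and 0 to 769 lower. The M6 apex ranged from 5 to 49 higher and 8 to 37 lower, the M6 bud from 11 to 1398 higher and 9 to 614 lower, the interaction from 0 to 1634 and the shared genes from 14 to 59. The camera p of the regulators lay between 0.00335 and 0.196 in AK58 bud against apex, between 0.111 and 0.829 in ZM7698 WT and between 0.0775 and 0.787 in the M6 apex. Its direction, not passed with all libraries, turned in ZM7698 WT without apex replicate 2 (0.829) or bud replicate 1 (0.706) and in the M6 apex without WT apex replicate 1 (0.787). It passed in AK58 without root replicate 1 (0.0122), root replicate 2 (0.0120), bud replicate 1 (0.00947) or bud replicate 2 (0.00335), all with the preset correlation. With all libraries that contrast gave p = 0.587 with an estimated correlation, which was not run with libraries left out. The AK58 ratios that passed ranged from 2 to 6.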

Other observations

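The tests of neighbouring genes, of the correlation on chromosome 5B and of shoot apex RNA and depth in root were chosen after the results were seen.

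Many of the genes called in M6 were close to absent in 1 genotype. In the apex 22 of 68 called genes (32.4%) had a mean under 0.1 TPM in the lower group, and in the bud 22 of 75 (29.3%). Among the 1271 genes called between bud and apex in ZM7698 WT, 137 (10.8%) did. Because fewer genes passed in M6, its calls needed a smaller unadjusted p than the bud and apex calls. The shares are therefore not like for like, and how far this raised the M6 shares was not tested.

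Genes called in M6 in both tissues form the first pattern. That the M6 bud library apart from its replicate produced it is argued against, since 33 genes were called in both tissues without M6 bud replicate 1. Among the 49 shared genes there were 9 neighbouring pairs within 5 tested genes, against a mean of 0.238 and at most 4 in 10000 random sets (permutation p = 1e-04, the smallest they can give). A run of several genes counts as several pairs, and these 9 pairs lay in few runs, on chromosomes 2A, 5B, 6B and 7D. Off chromosome 5B there were 5 pairs, against at most 3, and over the 93 genes called in either tissue there were 14, against at most 6. Chromosome segments that differ between the M6 line and the WT plants are therefore a candidate explanation, and loss of the SPL genes and shared regulation of neighbouring genes also stay open, untested. SVP1-6D is among the shared genes, though in none of these pairs, so these explanations stay open for it too.

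The share of M6 calls on chromosome 5B is the second pattern. Loss or gain of a whole copy of 5B is argued against by a median log2 fold change of all genes tested there of -0.0420 in the apex and 0.0403 in the bud. Across the 2636 uncalled genes on 5B, the fold changes in apex and bud correlated at r = 0.315, against 0.0115 to 0.242 on the other 20 chromosomes, across genes that are not independent replicates. That would be consistent with another haplotype of 5B in M6 than in the WT plants. An effect of the SPL mutations on genes of 5B stays open, and neither was tested against sequence.

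The AK58 root replicates form the third pattern: 16107 genes were over 4-fold higher in replicate 2 and 177 in replicate 1, against 126 to 435 genes apart in either direction in the other tissues. Leaf RNA in replicate 1 as the whole cause is argued against, since over the 100 most abundant leaf genes the 5th percentile of the ratio to leaf was 0.0191 and the median 0.134, where 0.996 would be needed. Shoot apex RNA in replicate 2 as the whole cause is argued against, since 71.5% of the genes higher there lay above both apex libraries as a share of all reads, and depth since the apex libraries, whose totals of 51497044 and 66843143 reads lay farther apart than 59268857 and 66785330 in root, had 404 genes over 4-fold apart. Replicate 1 correlated with the leaf libraries at r = 0.758 and 0.770, against 0.525 and 0.519 for replicate 2 and 0.770 between the root replicates, so a smaller share of leaf RNA in replicate 1 stays open. A different part or stage of the root in each replicate also stays open, and no biological explanation was tested.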
